A study of Mus musculus with 3 samples.

How the data were processed

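Polyadenylated RNA was sequenced from 1 sample of regulatory T cells (Tregs), from adult male mouse aged 6 months. The strain carries Cre-ERT2 at Foxp3 and a YFP reporter at Rosa26. The labels describe the cells as having experienced inflammation. The labels give 1 group, 1 biological replicate and 3 technical replicates, so the 3 libraries are called library 1, 2 and 3 after their technical replicate numbers. RNA was fragmented by shearing, per the labels. The labels do not say at which step the technical replicates were divided.

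Each library came with 3 tables. The first held estimated counts per gene with multi-mapped reads shared by a model, in the column layout that RSEM writes, per the file headers; it rests on the mm10 assembly and GENCODE M21, per the deposited description of each file. Its TPM values were made by the authors from the count and an effective length and are scaled to a common total over all entries of a library, per the file headers. The same table gives a posterior SD of each count, a signal in reads of how uncertain the assignment of reads was, as deposited. The second table held the same columns per transcript, with the percent of the gene's TPM that each transcript takes, per the file headers. The third held whole-number counts per gene on GENCODE M4, as deposited, with 22457 genes of which 22195 are shared with the first table. The aligner, the tool versions, the read length, the strand setting and the treatment of duplicate reads are not given in the sources used here.

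The first table had 81881 entries, of which 55536 were genes and all of these were found in the GENCODE M21 annotation used here. The other entries were 26248 transfer RNA entries without a gene identifier, 96 ERCC spike-in entries and phiX. These entered no test. Gene totals were 11829501, 14136139 and 10667765 estimated counts in libraries 1, 2 and 3. The whole-number tables summed to 2988262, 3386154 and 2734873. A gene at 0 counts is compatible with up to 3 counts, which was 0.254, 0.212 and 0.281 CPM in libraries 1, 2 and 3. Such floors and the 95% Wilson intervals printed here cover counting error only, because reads copied by PCR are not independent molecules. Where a symbol had several gene entries, the one with the highest mean count was used. Genes that overlap or share sequence with a near-identical copy are uncertain, since the model could split their reads.

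Estimated counts were rounded to whole numbers. With 1 group, edgeR's quasi-likelihood test could not be run, since it compares groups. Differences between the libraries were tested per gene with a Poisson chi-square test of homogeneity, with expected shares from TMM-adjusted library sizes (edgeR 4.0.16 in R 4.3.3), for the 13970 genes with a mean count of 10 or more, at a Benjamini-Hochberg adjusted p of 0.05. TMM factors were 0.995, 0.975 and 1.03 in libraries 1, 2 and 3. The chi-square is given divided by its degrees of freedom, where counting noise alone gives a mean of 1. The test treats reads as independent and therefore calls more genes than a test on molecules would. It describes these libraries and says nothing of other animals.

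A total of 34 gene lists with 521 genes, 28 pairs of genes and 30 genes for their transcripts were fixed before the data were examined, as were all tests and alternatives except those named as chosen later. A planned test of depth differences between libraries was dropped without being run. Another, of chance receptor clones, was added later and dropped because it could decide nothing. The annotation held 520 of the 521 list genes. A list was tested by its median chi-square per degree of freedom against 10000 random lists of the same size matched on mean count in 20 bins (permutation test, upper tail), with Benjamini-Hochberg adjustment over the 31 lists with at least 5 tested genes. List members were also adjusted over the list alone. A gene was called detected at 1 TPM or more in all 3 libraries. Pairs were compared within each library as the difference of log2(TPM + 0.1) and tested with an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25. The log2(TPM + 0.1) scale understates differences of genes at low levels. The rank of a list is the percentile of its median log2(TPM + 0.1) among 10000 random lists of the same size. These were drawn from genes at 1 TPM or more in at least 1 library. List members under that limit were kept, so lists that hold such members can rank low for that reason. Levels are means ± SD over the 3 libraries.

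Genes named in the text follow a rule fixed in advance. It takes up to 4 members of each list with the highest mean TPM and members under 1 TPM that the list is known for. It adds all genes of the pairs and the 15 genes with the highest mean TPM, leaving out mitochondrially encoded genes, ribosomal protein genes and pseudogenes. It also adds the 20 genes with the largest chi-square per degree of freedom among those with an adjusted p under 0.05 and a mean count of 100 or more, and genes of the transcript table whose leading transcript differs between libraries or is not the longest. Any other gene is said to be chosen after its values were seen. Some genes that the rule takes, and the pairs that hold them, are not reported here, although they count in the totals over lists and pairs.

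The chi-square test was tested on simulated Poisson counts for the 13970 genes at their real means, with 200 genes changed in 1 library. It recovered 70% of genes changed 1.5-fold, 78% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 9 false calls. The list test, on simulated counts of the same 13970 genes, called 0 lists when nothing differed. It called 1 list, the changed one, when the B cell list was doubled in 1 library. Unchanged simulated genes held counting noise alone, with a median chi-square per degree of freedom of 0.691 against 3.28 in the data. These simulations therefore do not show how often either test errs where reads are duplicated or genes vary together. The rank placed a list of 20 genes drawn from the most abundant of 16115 genes at percentile 100. The comparison of gene tables found 100% of genes changed 4-fold among 8940 genes and called 0 of the others. The slope of whole-number on estimated counts across libraries told simulated counts that were a fixed fraction of the estimated ones from counts fixed per gene.

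Alternatives were DESeq2 size factors (DESeq2 1.42.0), total counts without a factor, other count and TPM limits, other pseudocounts, CPM without length, the whole-number table, another background for the rank and leaving out each library. After the data were seen, 3 settings were added for the count of differing genes: the squared posterior SD added to the variance, the chi-square scaled by 0.439, the median ratio of the whole-number to the estimated counts at low read density, and the test without receptor, immunoglobulin and haemoglobin genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are those of mm10, 1-based.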

Results

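Tregs are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. Messenger RNA of Tregs that had gone through inflammation was measured in 3 libraries of 1 biological replicate. These held 11829501, 14136139 and 10667765 estimated counts on genes in libraries 1, 2 and 3. Resting and activated Tregs were not analysed here, so the account covers the levels in these cells and the differences between their libraries. Nothing in the labels says that the libraries came from separate animals. Gene p-values set differences between these libraries against counting noise. List p-values set a list against random genes and treat its members as independent, although they can vary together. Only the pair test uses the spread between libraries, and no p-value measures the spread between animals.

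Treg genes were abundant in all 3 libraries. Of the 24 genes of the Treg core list, 22 were detected, and the list ranked at percentile 100 among random lists of the same size. Tigit, a co-inhibitory receptor, stood at 685 ± 25.3 TPM (SD, n = 3), Tnfrsf4 (OX40) at 657 ± 123, the actin-capping gene Capg at 538 ± 80.9 and Tnfrsf18 (GITR) at 537 ± 54.6. Ikzf2, which encodes the Treg factor Helios, reached 433 ± 55.7 TPM over all its transcripts, of which the retained-intron transcript Ikzf2-205 took 51.8% on average. Foxp3 itself (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245) was lower, at 16.1 ± 1.86 TPM from 259, 247 and 216 counts in libraries 1, 2 and 3, and its counts did not pass the test for a difference between libraries. Plagl1 alone of the list was under 1 TPM in all libraries, at 0.22 ± 0.111 TPM.

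Genes of suppression and activation were also high. The suppressive mediators list had 20 of 21 members detected, led by Lgals1 (galectin-1) at 2036 ± 327 TPM, Penk (proenkephalin) at 695 ± 244, Tigit and Pdcd1 (PD-1) at 282 ± 2.97. Gzmb, a granule protease, stood at 248 ± 54.7 TPM and Ctla4 at 124 ± 25.3. Il10 was at 8.31 ± 2.66 TPM and Tgfb1 at 5.13 ± 1.85, while Il12a stayed at 0.283 ± 0.249. The activated or effector Treg list had 27 of 28 members detected, with Srgn (serglycin) at 1831 ± 47 TPM, the HLH factor Id2 at 1178 ± 63.3, S100a6 at 1027 ± 136 and Anxa2 at 466 ± 110. Only Pparg of that list was under 1 TPM in all libraries, at 0.743 ± 0.0451.

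All 24 proliferation genes were detected, led by Hmgb2 at 871 ± 167 TPM, Stmn1 at 475 ± 106, the ribonucleotide reductase subunit Rrm2 at 397 ± 81.6 and Tyms at 274 ± 58.8. The interferon-stimulated list had 25 of 25 detected, with Ifi27l2a at 1233 ± 122 TPM, Ly6a at 921 ± 110 and Igtp at 219 ± 18.3. Glycolysis genes, 19 of 19 detected, were led by Ldha at 985 ± 133 TPM, Pkm at 841 ± 88.9, Aldoa at 654 ± 25.9 and Eno1 at 456 ± 61.6. All these lists ranked at percentile 100 in each library. Immediate early and heat shock genes, which can rise during cell isolation, had 24 of 27 detected and ranked at percentile 94.9 on average, led by Hspa8 at 2623 ± 347 TPM and Nfkbia at 447 ± 63.8, with Hsp90aa1 at 221 ± 20.7 and Btg2 at 138 ± 5.33. NF-kappaB pathway genes were all detected, 20 of 20, and ranked at 99.8. Among fatty acid oxidation and uptake genes, 14 of 18 were detected, led by Etfb at 212 ± 19.1 TPM and Etfa at 139 ± 3.02, and the uptake gene Cd36 stood at 0.487 ± 0.388. Apoptosis regulators, 17 of 18 detected, were led by Bcl2a1b at 312 ± 20.9 TPM, Bcl2a1d at 197 ± 24.7, Bax at 138 ± 5.41 and Casp8 at 119 ± 9.73; Bcl2a1b and Bcl2a1d are near-identical copies whose split is uncertain.

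Genes of other T helper programmes were unevenly present. The Th1-associated list had 15 of 17 members detected and ranked at percentile 99.8, with the chemokine Ccl5 at 2946 ± 1906 TPM, Nkg7 at 1322 ± 614 and Ifngr1 at 306 ± 15.9. Ifng was at 41.4 ± 14.4 TPM. Tfh-associated genes, 13 of 14 detected, were led by Sh2d1a at 293 ± 29.1 TPM and Izumo1r, the folate receptor 4 gene, at 284 ± 53.4, with Slamf6 at 254 ± 9.74. The Th17-associated list ranked at 25.8 with 13 of 16 detected, and the Th2-associated list at 45.2 with 10 of 16. The lists held 1 and 5 members under 1 TPM in all libraries, which the random lists could not hold. Against random lists drawn from all genes above 0, these ranks became 97.5 and 98.5. Batf led the former at 226 ± 9.82 TPM, followed by Rora at 82 ± 5.92, while the cytokines Il17a and Il17f were at 0.323 ± 0.492 and 0.87 ± 0.272 TPM. Gata3 led the latter at 136 ± 17 TPM, with Stat6 at 123 ± 4.65 and Maf at 111 ± 10. Il5, Il9 and Il13 had at most 2 counts in any library, with Il9 at 0 in all 3. The list of genes lowered in Treg relative to conventional CD4 T cells ranked at 49.5, or at 99.0 against that background, with Tcf7 at 119 ± 17.9 TPM, Lef1 at 80.2 ± 1.8, Themis at 64.1 ± 12.4 and Cd40lg at 57.6 ± 11.5.

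Among chemokine receptors and homing molecules, 26 of 31 were detected, led by Cxcr6 at 451 ± 7.52 TPM, Selplg at 451 ± 55.3, Itgb7 at 427 ± 37.5 and Itgb2 at 390 ± 47.8. Cytokine receptors, 28 of 29 detected, were led by the common chain Il2rg at 1243 ± 41.9 TPM, Il2rb at 523 ± 56, Ifngr1 and Il27ra at 163 ± 13.6. The TNF receptor superfamily had 15 of 18 detected, with Cd27 at 185 ± 17.9 TPM and Tnfrsf25 at 121 ± 19.2 after Tnfrsf4 and Tnfrsf18. The resting or central lymphocyte list had all 18 detected, led by S1pr1 at 126 ± 18.8 TPM, Tcf7, Id3 at 103 ± 3.64 and Il7r at 102 ± 30.8. T cell identity genes, 20 of 20 detected, were led by the receptor constant genes Trbc2 at 3650 ± 22.6 TPM, Trac at 2910 ± 86.3, Trbc1 at 1628 ± 308 and by Cd3g at 1481 ± 84.6.

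Markers of other cell types were mostly low, though this depends on the background, and several were uneven between libraries. Against random lists drawn from all genes above 0, their ranks ran from 0.72 (stromal, endothelial and epithelial) to 93.2 (CD8 T cell) and 93.3 (B cell). The CD8 T cell and B cell lists ranked at 48.5 and 35.1 against genes at 1 TPM or more. In the B cell list, 21 of the 22 tested members were lowest in library 1. Cd74, which T cells can also express, was at 573 ± 147 TPM, Ighm at 391 ± 36.8 and Igkc at 253 ± 186, the latter at 45.3, 308 and 405 TPM in libraries 1, 2 and 3. The plasma cell gene Jchain had 12, 289 and 251 counts in libraries 1, 2 and 3 and the haemoglobin gene Hbb-bs 6, 113 and 518, with Hba-a2 at 0, 109 and 446. Lyz2, abundant in myeloid cells, had 17, 441 and 123 counts. Cd8a had 2, 23 and 48 counts and Cd8b1 75, 179 and 147. NK-associated Prf1 (perforin) was at 7.49, 25.2 and 6.73 TPM and Tyrobp at 1.5, 11.9 and 3.98. Detected members numbered 13 of 22 in the B cell list, 4 of 14 for plasma cells, 5 of 13 for erythroid cells, 5 of 20 for macrophages and monocytes, 6 of 15 for NK cells, 4 of 6 for CD8 T cells, 4 of 9 for gamma-delta T cells, 5 of 14 for dendritic cells, 1 of 17 for neutrophils and granulocytes, 1 of 10 for platelets and megakaryocytes, 2 of 18 for stromal, endothelial and epithelial cells and 3 of 9 for thymocytes. Several detected members are genes that T cells also express, such as Ctss at 208 ± 29.3 TPM and Ccr2 at 161 ± 21.9 in the macrophage list, Cst3 at 178 ± 3.97 in the dendritic cell list, Pecam1 at 38.1 ± 2.88 in the stromal list and Cd4 in the thymocyte list. In the CD8 T cell list, Runx3 at 17.5 ± 3.34 TPM and Zbtb7b at 13.3 ± 1.91 are genes that CD4 T cells also express. Runx3 is in the Th1-associated list too. The detected count and ranks of the CD8 T cell list therefore do not measure CD8 T cells alone. Y-linked Ddx3y at 84 ± 2.63 TPM and Eif2s3y at 119 ± 22.5, against Xist at 0.1 ± 0.07, matched the male sex in the labels.

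**Figure D1:**
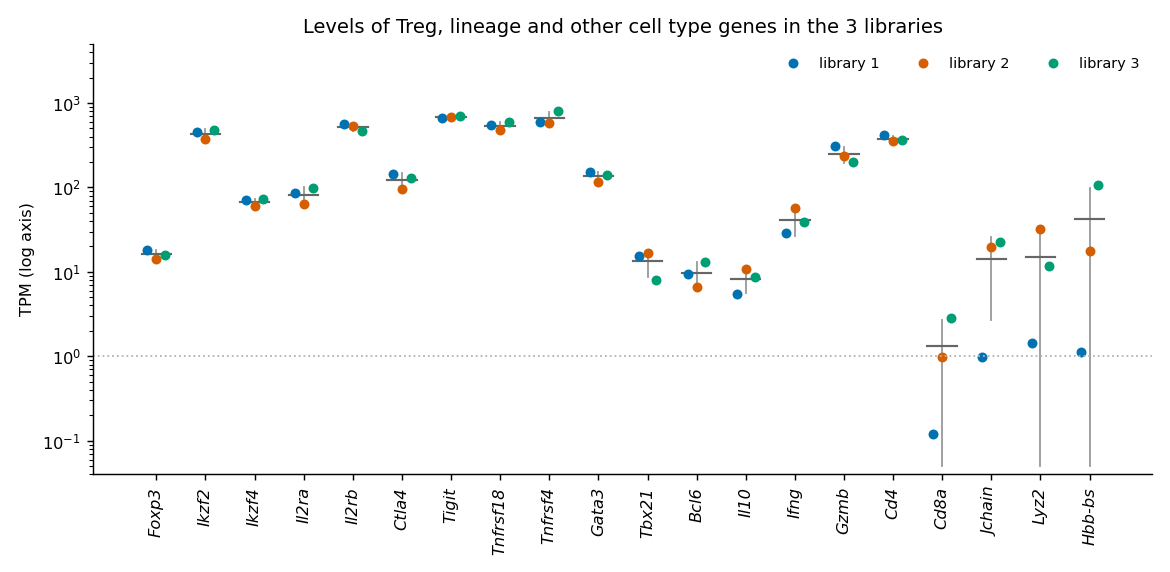
TPM (log axis) of Treg genes, lineage factors, cytokines and markers of other cell types in libraries 1, 2 and 3; points are libraries, horizontal bars means and grey lines 1 SD, drawn down to the lower edge at most, and the dotted line marks 1 TPM. Foxp3, at 16.1 TPM on average, lies under Ikzf2 and Tigit, and the CD8 T cell, plasma cell, myeloid and erythroid markers at the right are lowest in library 1.

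Of the 28 pairs of related genes, 26 had the same sign in all 3 libraries, which gives an exact sign-flip permutation p of 0.25, the smallest possible with 3 libraries; no pair could therefore pass a limit of 0.05. Among lineage factors, the log2 difference Foxp3 minus Ikzf2 was -4.74 ± 0.131 (SD, n = 3) and Foxp3 minus Gata3 -3.07 ± 0.0373, and Gata3 lay above Tbx21 (T-bet, 13.4 ± 4.62 TPM) by 3.39 ± 0.642. Foxp3 was above Bcl6 (9.73 ± 3.2 TPM) by 0.76 ± 0.417, and the sign turned without length adjustment, to -0.35. The difference Foxp3 minus Tbx21, at 0.32 ± 0.604, changed sign between libraries. Ikzf2 exceeded its relatives on the TPM of whole genes, above Ikzf4 by 2.67 ± 0.0607, with Ikzf1 minus Ikzf2 at -2.16 ± 0.319. Retained-intron transcripts Ikzf2-205 and Ikzf2-203 held 51.8% and 7.90% of Ikzf2 TPM. Foxp3-207, annotated as a nonsense-mediated decay transcript, held 75.2% of Foxp3 TPM. Differences with either gene are therefore of whole genes, and those between coding transcripts were not computed. Prdm1, the gene of BLIMP1, minus Tcf7 was -2.43 ± 0.451, Prdm1 lay above Bach2 by 3.02 ± 0.919, and Id2 lay above Id3 by 3.52 ± 0.066. The sizes depend on the scale: without length adjustment Foxp3 minus Ikzf2 was -6.24, and in the whole-number counts, also without length, it was -2.72. In the latter, where abundant genes keep few counts, Ikzf2 lay above Ikzf4 by only 0.46 and Id2 above Id3 by 1.51, with Ikzf1 minus Ikzf2 at -0.39 and Prdm1 minus Tcf7 at -0.49.

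Homing receptor pairs gave Cxcr3 above Ccr7 by 4.21 ± 0.447 log2 units and above Ccr6 by 2.75 ± 0.6, and Ccr8 above Ccr4 by 1.52 ± 0.245. Among mediators, Il10 minus Ifng was -2.30 ± 0.128 and Tgfb1 minus Il10 -0.69 ± 0.742, the latter smaller in size than its SD. Ebi3, a subunit of IL-27 and IL-35, was at 58.9 ± 16.3 TPM against Il12a, which had 0, 4 and 4 counts. Gzmb exceeded Gzma by 3.05 ± 0.217, and Nt5e (CD73) exceeded Entpd1 (CD39) by 1.11 ± 0.541. Ctla4 minus Cd28 was -0.66 ± 0.326 and Tigit lay above its competitor Cd226 by 2.02 ± 0.0731. The interleukin-2 receptor beta chain Il2rb exceeded Il7r by 2.4 ± 0.561, and Il2ra minus Il2rb was -2.68 ± 0.426. Cd4 exceeded Cd8a by 8.74 ± 1.98, the spread coming from Cd8a. Trbc2 exceeded Trbc1 by 1.18 ± 0.27. Without length adjustment Ccr8 lay above Ccr4 by 0.53, Tigit above Cd226 by 0.97 and Nt5e above Entpd1 by 2.10, with Ctla4 minus Cd28 at -1.69 and Tgfb1 minus Il10 at -0.19. In the whole-number counts Tigit lay above Cd226 by 0.80 and Trbc2 above Trbc1 by 0.20.

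Actb, the gene of beta-actin, was the most abundant at 52365 ± 2148 TPM, or 3.03%, 3.14% and 2.83% of counts in libraries 1, 2 and 3 (95% intervals 3.02 to 3.04, 3.13 to 3.15 and 2.82 to 2.84), followed by Tmsb4x at 11964 ± 779. B2m stood at 7918 ± 447 TPM, Eef1a1 at 6173 ± 144, Malat1 at 4754 ± 551, H2-K1 at 4172 ± 284, Ubb at 4124 ± 89.7, Pfn1 at 3535 ± 370, Actg1 at 3461 ± 601 and Rac2 at 3408 ± 99.7, and Trbc2 fell in the same range. CT010467.1 at 9757 ± 853 TPM and AY036118 at 9529 ± 1408 overlap on chromosome 17, and Gm37376 at 3465 ± 469 overlaps Malat1 on chromosome 19, so how reads were split within each pair is uncertain. Mir6236 was at 3663 ± 400. The housekeeping list was detected in full, 12 of 12.

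The 3 libraries differed by more than counting noise in 6388 of 13970 tested genes, 45.7%, with a median chi-square per degree of freedom of 3.28. Of these, 1387 differed over 2-fold between the highest and lowest library and 3942 under 1.5-fold. Library 1 was highest in 1959 of them, library 2 in 2165 and library 3 in 2264. With total counts in place of TMM the shares highest in libraries 1, 2 and 3 were 28.5%, 22.3% and 49.1%, against 30.7%, 33.9% and 35.4%. The whole-number table called 2154 genes, and without library 3 the estimated counts called 2978. The edgeR common dispersion with an intercept alone gave a coefficient of variation of 16.9% between libraries.

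Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), a chemokine of effector T cells, showed the largest chi-square per degree of freedom, 6133, at 1426, 5085 and 2327 TPM in libraries 1, 2 and 3. Nkg7, a cytotoxic granule gene, stood at 1142, 2006 and 819 TPM, the granule protease gene Gzmk at 5.66, 202 and 53.7 and Plek at 33.4, 85.2 and 21.6, all highest in library 2 in the estimated counts. On the log2 scale library 1 lay farthest from the others for Gzmk, and library 2 for the other 3. Library 2 also stood apart for the receptor segment Trbv1, at 43.8, 340 and 73.0 TPM, for Gimap4 at 1484, 1661 and 1340 and for CT010467.1. Penk, at 439, 718 and 926 TPM, Igkc, AY036118 and Gm26917 (uncertain, beside CT010467.1 and AY036118), at 306, 429 and 542 TPM, were lowest in library 1. Trbv13-3, at 143, 62.4 and 412 TPM, and Ttn, at 6.79, 7.12 and 11.3, were highest in library 3. Actb, Actg1, Hspa8, Lcp1 and Tmsb4x were lowest in library 3 by small margins, from 1.17-fold for Actb and 1.18-fold for Tmsb4x to 1.44-fold for Actg1 between the highest and lowest library. Actg1 and Tmsb4x did not pass in the whole-number table, where they held only 64, 74 and 59 and 464, 468 and 453 counts in libraries 1, 2 and 3, so that this says little about either. Relative to library size, the whole-number counts of Ccl5, Nkg7, Gimap4, Actb, Hspa8, Lcp1 and Tmsb4x were instead lowest in library 2 and highest in library 3. Nkg7 had 1091, 1118 and 1030 counts there, or 371, 331 and 376 CPM (counts relative to library size). Abundant genes keep few counts in that table, where Ccl5 had 613, 655 and 638 counts in libraries 1, 2 and 3. The order there therefore says little about these genes, whose order rests on the estimated counts alone. Gzmk, Plek and Trbv1 were highest in library 2 in both tables. The mitochondrial gene mt-Co3 and Gm28437, a pseudogene of a mitochondrial sequence, did not pass once the posterior SD of their counts was added, and Gm28437 did not pass without library 2 either.

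**Figure D2:**
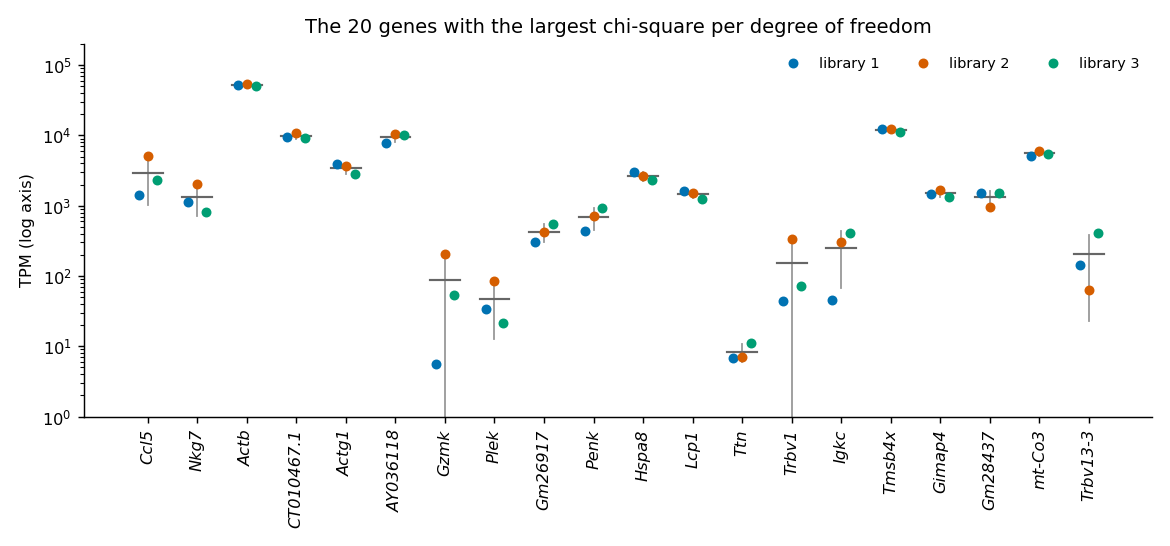
TPM (log axis) in libraries 1, 2 and 3 of the 20 genes with the largest chi-square per degree of freedom at a mean count of 100 or more, in that order; points are libraries, horizontal bars means and grey lines 1 SD, drawn down to the lower edge at most. Ccl5, Nkg7, Gzmk and Plek are highest in library 2 in the estimated counts, whereas abundant genes such as Actb differ by 1.17-fold.

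Proliferation genes were lowest in library 3 in all 24 tested members, under TMM, DESeq2 and total-count scaling alike, and in 23 of 24 in the whole-number table. All 24 passed the gene-level test, also adjusted over the list alone, and the list varied beyond random lists (permutation adjusted p = 0.000344; unadjusted 0.0001, the smallest the permutations can give). Hmgb2 stood at 976, 958 and 678 TPM in libraries 1, 2 and 3, Stmn1 at 561, 506 and 357, and Rrm2 at 482, 392 and 319. Glycolysis genes were lowest in library 3 in 15 of 19 members (permutation adjusted p = 0.0062), with Ldha at 1113, 993 and 847 TPM. In this list 17 passed, 17 adjusted over the list alone. It was not called without library 1 or without library 3 (permutation adjusted p = 0.151 and 0.0762). With whole-number counts library 3 was lowest in 6 of 18 members and library 2 in 7. Abundant genes keep few of their counts there. The proliferation list kept its order at a higher median level, 95.2 TPM against 71.9. List medians cannot show how many counts single genes lost, so this does not tell whether that loss moved the glycolysis list. The direction of the glycolysis list rests on the estimated counts and stays open. Library 3 also held the highest haemoglobin counts, with Hbb-bs at 518.

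Th1-associated genes were highest in library 2 in 14 of 16 tested members (permutation adjusted p = 0.000344). All 16 passed, also adjusted over the list alone. With whole-number counts, of which abundant genes keep few, library 2 was highest in 8 of 16. The proliferation list kept its order there at a higher median level, 95.2 TPM against 54.5, but list medians cannot show how many counts single genes lost. The direction of the Th1 list therefore rests on the estimated counts. Ifng stood at 28.6, 57.0 and 38.5 TPM in libraries 1, 2 and 3. Interferon-stimulated genes were highest in library 2 in 20 of 25 members under TMM, with Ifi27l2a at 1133, 1368 and 1197 TPM, and 19 passed, 19 adjusted over the list alone (permutation adjusted p = 0.000344). The list was not called without library 2 (permutation adjusted p = 0.649). Myeloid Lyz2 and NK-associated Prf1 were highest in library 2 too, and the NK cell list, with 7 of 9 tested members passing, 7 adjusted over the list alone, and the macrophage and monocyte list, with 9 of 10, 10 adjusted over the list alone, both varied beyond random lists (permutation adjusted p = 0.000344 each). Neither was called without library 2 (permutation adjusted p = 0.0801 and 0.115).

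Treg core genes were lowest in library 2 in 13 of 23 tested members, and 21 passed, 21 adjusted over the list alone (permutation adjusted p = 0.000344). Ctla4 stood at 146, 96.4 and 130 TPM in libraries 1, 2 and 3, Il2ra at 85.5, 63.3 and 98.1 and Ikzf2 at 451, 371 and 478. Library 2 was also highest for 7 of 9 tested NK cell genes, 7 of 10 macrophage and monocyte genes and Gzmk, at 47, 2130 and 440 counts, so lower levels within Tregs and a different mixture of cells in library 2 were not separated. Without library 2 the list was not called (permutation adjusted p = 0.955). The suppressive mediators (20 of 20 members passing, 20 adjusted over the list alone), chemokine receptors and homing molecules (26 of 29, 27 alone), cytokine receptors (23 of 29, 24 alone), and Tfh-associated genes (14 of 14, 14 alone) were called with permutation adjusted p = 0.00103, 0.000344, 0.00269 and 0.00542, and none of them without library 2 (permutation adjusted p = 0.193, 0.318, 0.354 and 0.0507). Pdcd1 at 283, 284 and 279 TPM and Cxcr6 at 443, 451 and 458 differed little, while Itgb2 stood at 423, 411 and 335.

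The activated or effector Treg list (23 of 28 members passing, 24 adjusted over the list alone; permutation adjusted p = 0.00244) was not called without library 1 or library 3 (permutation adjusted p = 0.0774 and 0.135), nor was the Th17-associated list (10 of 13, 11 alone; permutation adjusted p = 0.00706; 0.0774 and 0.0671), which also missed at a mean count of 100 (permutation adjusted p = 0.0664). The resting or central lymphocyte list (14 of 18, 15 alone; permutation adjusted p = 0.0162) was not called without library 2 or library 3 (permutation adjusted p = 0.401 and 0.061). Genes lowered in Treg relative to conventional CD4 T cells (11 of 14, 12 alone) passed at a permutation adjusted p of 0.0493 and missed at 0.0508 with DESeq2 size factors; Tcf7 stood at 103, 115 and 138 TPM in libraries 1, 2 and 3. Immediate early and heat shock genes (21 of 26, 21 alone; permutation adjusted p = 0.00215) were highest in library 3 in 13 members, among them Nfkbia at 391, 434 and 516 TPM, and Hspa8 was lowest there.

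The B cell list (21 of 22 tested members passing, 21 adjusted over the list alone), the erythroid list (6 of 7, 6 alone), the plasma cell list (8 of 9, 8 alone) and the CD8 T cell list (5 of 6, 5 alone) varied beyond random lists (permutation adjusted p = 0.000344, 0.000344, 0.00062 and 0.00103). The plasma cell list was not called without library 1 (permutation adjusted p = 0.193). The lists not called were T cell identity (18 of 20 members passing, 18 alone), Th2-associated (8 of 12, 9 alone), TNF receptor superfamily (8 of 15, 8 alone), NF-kappaB pathway (10 of 20, 10 alone), fatty acid oxidation and uptake (8 of 16, 9 alone), apoptosis regulators (12 of 18, 12 alone), gamma-delta T cell (2 of 5, 2 alone), dendritic cell (2 of 8, 4 alone), stromal, endothelial and epithelial (3 of 5, 3 alone), sex check (4 of 6, 4 alone) and housekeeping (11 of 12, 11 alone), with permutation adjusted p between 0.105 and 0.885. Of these, the Th2-associated list was called without library 1 and without library 3 (permutation adjusted p = 0.045 and 0.0201). In total 20 of 31 lists were called, and 11 without library 2.

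**Figure D3:**
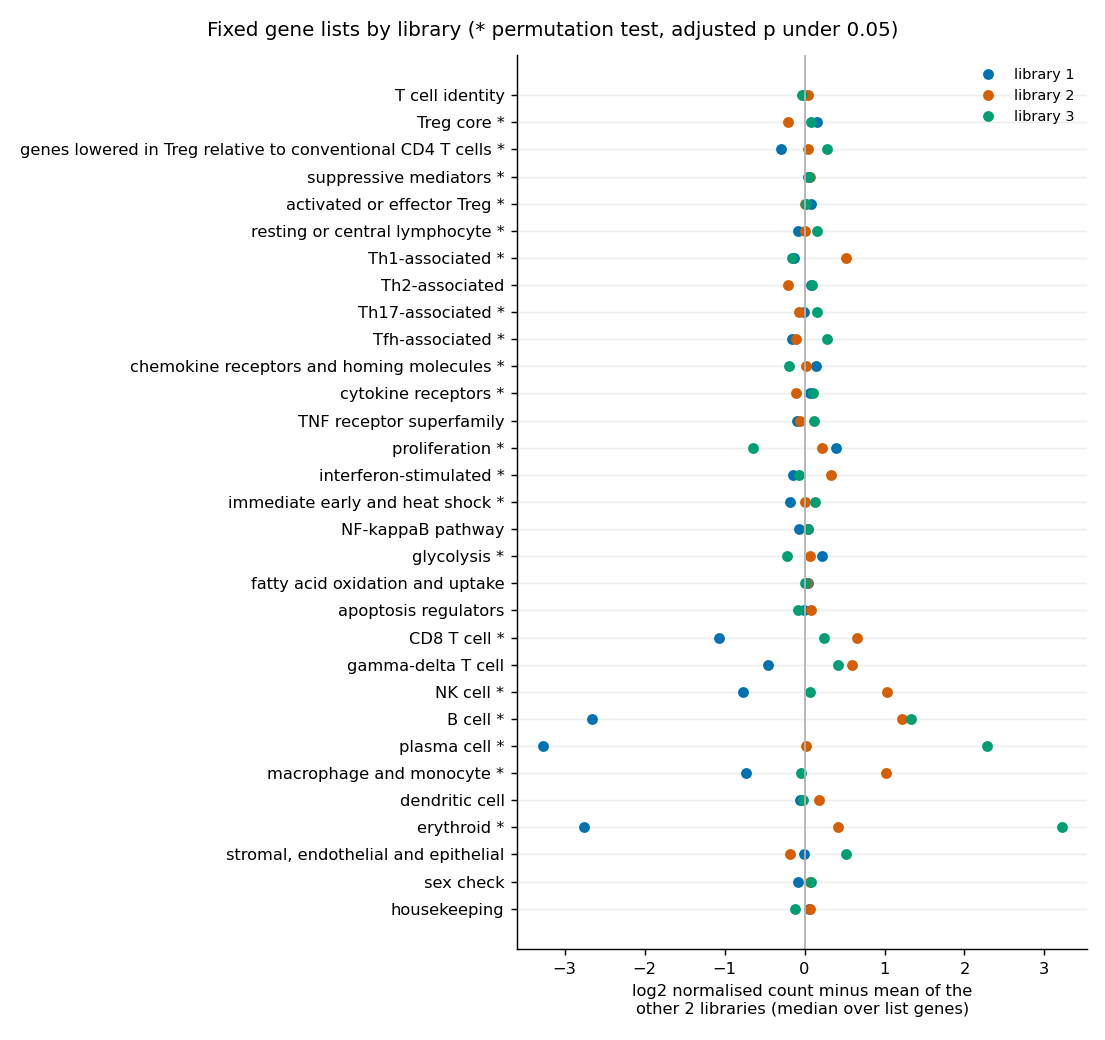
Median over the tested genes of each fixed list of the log2 normalised count in 1 library minus the mean of the other 2 (horizontal axis, log2 units), for libraries 1, 2 and 3; stars mark lists that varied beyond random lists. Proliferation lies at -0.65 in library 3, Th1-associated genes at 0.51 in library 2 and the B cell list at -2.66 in library 1.

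One transcript led in all 3 libraries in 28 of the 30 genes examined, among them Il10, which has 1 annotated transcript and could not differ, and in 14 of the 30 the leading transcript was not the longest annotated one. For Foxp3 the leading transcript was Foxp3-207 (ENSMUST00000234479.1, chromosome X, 7579669 to 7593105), of 1557 bases and annotated as a nonsense-mediated decay transcript, with 75.2% ± 1.27 of the gene's TPM (SD, n = 3). Foxp3 transcripts that reach the distal 3′ UTR end, 7595234 to 7595245, well past the stop codon at 7593041, held 3.68, 4.48 and 4.86 counts in libraries 1, 2 and 3, or 1.83% ± 0.414 of Foxp3 counts. In Ikzf2 the retained-intron transcript Ikzf2-205 (1905 bases) led with 51.8% ± 4.26 of TPM, although the coding transcript Ikzf2-201 (9278 bases) held more counts, 13970, 14249 and 12221 against 3764, 3690 and 4175, because shares are adjusted for length. Ptprc, which encodes CD45, was led by Ptprc-203 at 42.6% ± 2.26, Cd44 by Cd44-207 at 63.6% ± 3.77, Fas by Fas-201 at 77.5% ± 4.2 and Tnfrsf9 by Tnfrsf9-204 at 35.1% ± 0.411.

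Rora was led by the short Rora-202 at 81.9% ± 0.805, Il6ra by Il6ra-201 at 93.2% ± 2.88, Nrp1 by Nrp1-201 at 75.3% ± 2.29, Lef1 by Lef1-203 at 74.9% ± 2.4, Lrrc32 by Lrrc32-201 at 70.8% ± 9.9, Bcl2l1 by Bcl2l1-201 at 51.8% ± 8.43 and Tnfrsf4 by Tnfrsf4-201 at 85.1% ± 0.475. The exceptions to a shared leader were Il1rl1, the gene of the IL-33 receptor, where Il1rl1-202 held 61.9%, 30.1% and 33.8% in libraries 1, 2 and 3, and Bach2, where Bach2-207 had the highest mean share, 31.4% ± 11.7, but led in no library; Bach2 rested on 71, 86 and 120 counts. Which transcript a read belongs to was estimated, so these shares carry model error beyond the SD.

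**Figure D4:**
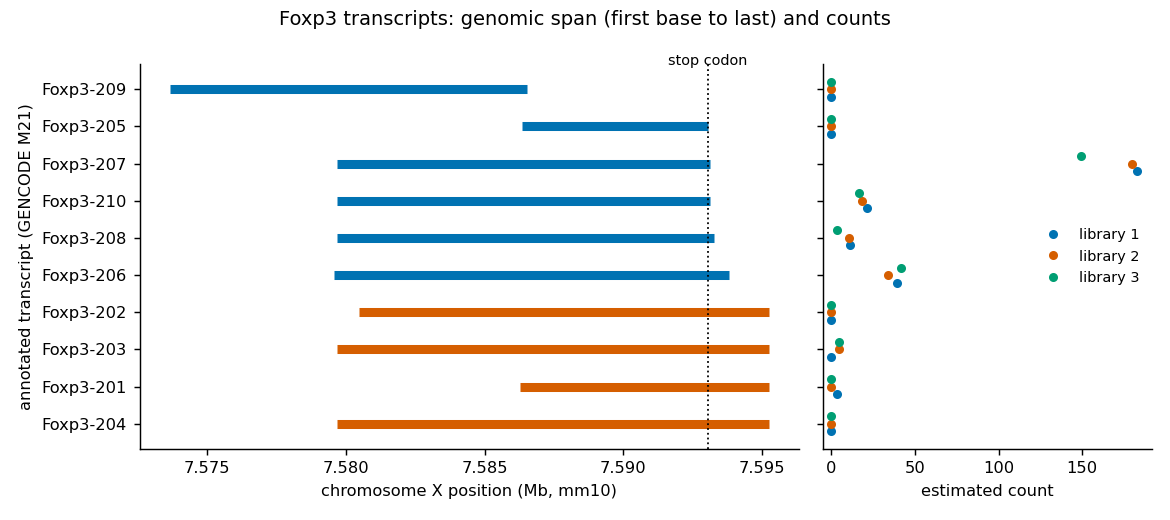
Left, genomic span in Mb on chromosome X (mm10) of the annotated Foxp3 transcripts, orange for those that reach the distal 3′ UTR end, with the stop codon dotted; right, estimated counts in libraries 1, 2 and 3. Foxp3-207 holds 183, 180 and 149 counts, and the 4 transcripts with the distal end hold 3.68, 4.48 and 4.86 together.

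The whole-number and the estimated gene tables ranked genes similarly but differed in scale. Across the 22195 shared genes, which are not independent replicates, Spearman's correlation within a library was 0.931 ± 0.00753 (SD, n = 3), and 0.836 for genes at 1 TPM or more. After scaling to a common total, 8785 ± 523 genes differed over 2-fold between the tables. Actb had 1929, 1947 and 1923 whole-number counts in libraries 1, 2 and 3 against 358898, 445299 and 302592 estimated counts, and Trbc2 had 584, 604 and 596 against 21187, 25528 and 19620. Ccl5, with 613, 655 and 638 whole-number counts, was nearly level there. Gzmk, with 32, 977 and 270, kept its order, and Foxp3 had 178, 186 and 150.

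**Figure D5:**
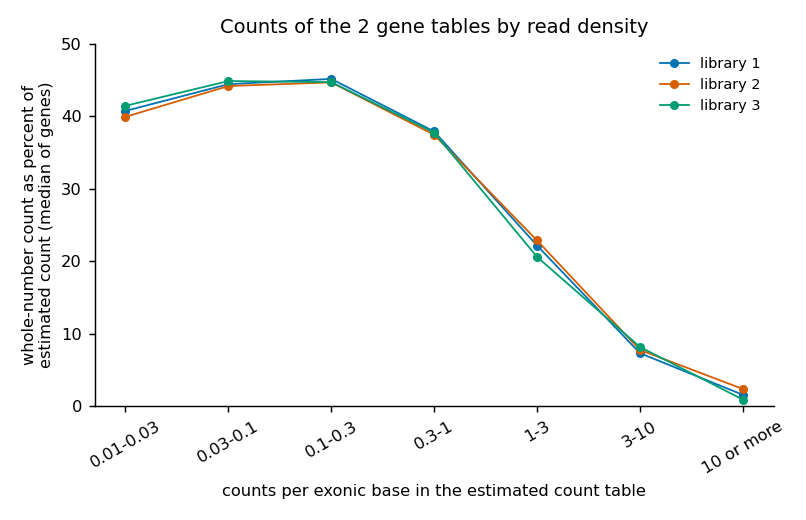
Median over genes of the whole-number count as a percent of the estimated count (vertical axis) by estimated counts per exonic base (horizontal axis, bins), with a line for each library. The median lies near 45% in genes with 0.1 to 0.3 counts per base and at 1.56%, 2.37% and 0.905% in libraries 1, 2 and 3 at 10 or more.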

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

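Groups of 3 libraries are too small for a test of single outlying libraries, so phiX and transfer RNA are given here as signals in entries that no comparison used. The tests of receptor V genes against duplicates and shared reads, and of 3′ UTR coverage, were chosen before their results were seen; those of separate cells, the reporter allele, read removal and the older annotation were chosen after.

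PhiX, a viral sequence added to sequencing runs as a control, had 32105, 31473 and 25900 counts in libraries 1, 2 and 3, above the 3 counts that an empty entry allows. These were 0.271% (95% interval 0.268 to 0.274), 0.222% (0.22 to 0.225) and 0.242% (0.239 to 0.245) of all counts. Transfer RNA entries held 1811, 1775 and 1905 counts.

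T cell receptor V genes, the segments that differ between T cell clones, varied between the 3 libraries of 1 biosample: 92 of 105 tested V genes passed, with a median chi-square per degree of freedom of 20.9 against 2.56 in random lists matched on mean count. The values argue against PCR duplicates as the whole cause, since the matched random lists carry duplicates too; the median of 11.3 over the 61 V genes tested in the whole-number table, above the limit of 3 set in advance, adds to this only if that table lacks duplicates, which no source used here states. They argue against reads shared between near-identical V genes as the whole cause too, since the median was 9.62 with the squared posterior SD added. With that setting 68 of the 105 V genes passed, and the median over all tested genes moved only from 3.28 to 2.86. An added variance can only lower the chi-square, so this fall does not show how much of the V gene variation comes from read assignment. Separate samples of cells behind the libraries stay open as a hypothesis: the 7 tested receptor C genes lay at percentile 59.1 of matched random lists, but they decide nothing, since Trbc1 and Trbc2 are alternatives between clones and Tcrg-C1, Tcrg-C2, Tcrg-C4 and Trdc belong to gamma-delta T cells. The design has 1 group, so no biological explanation was tested.

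Few Foxp3 counts fell on transcripts with the distal 3′ UTR end, 1.83% on average. The limit set in advance leaves low coverage of distal 3′ ends open, although coverage was not low at the median gene. The median of 1627 protein-coding genes with ends at least 1000 bases apart held 58.5% on its distal end. Foxp3 lay at percentile 6.88 of these genes, above the limit of 5 set in advance. Low coverage at Foxp3 and other genes at the low end thus stays open. The reporter allele of this strain, which places Cre-ERT2 in the Foxp3 gene, could also interrupt the 3′ UTR. The share of 1.83% is what this needs, but no entry for reporter sequence was present. The allele therefore cannot be told apart from low coverage at this gene. No biological explanation was tested.

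Abundant genes held few counts in the whole-number table. The values argue against the older annotation behind that table as the whole cause, since 1 annotation serves all libraries and counts of a gene would then follow its estimated counts between them. The slope of log2 whole-number on log2 estimated counts was 0.177 (bootstrap 95% interval 0.11 to 0.264) over 164 of the 193 genes at 3 or more counts per base, without those near the floor of that table, against 1.07 at low density. Removal of reads that start at the same position is a candidate explanation: 0 of 22083 genes of at least 200 exonic bases exceeded 2 counts per base in any library. That limit was chosen after the values were seen, so the count of 0 adds no support. Actg1, at 64, 74 and 59 counts against 66820, 76179 and 43234 estimated, lay far under it. So did mt-Co3, at 0, 1 and 0 against 34289, 48837 and 32979, for a cause that was not tested. No source used here states such a step, and no biological explanation was tested.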

How the results depend on the processing

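Settings added after the data were seen were the posterior SD, the scaled chi-square and the test without receptor, immunoglobulin and haemoglobin genes. The 6388 differing genes fell to 2154 in the whole-number table, which tested 9991 genes with fewer counts, and to 2595 with the scaled chi-square, which is smaller by construction; they ranged from 2978 to 4765 without 1 library, lowest without library 3. The other settings gave between 4833 and 7055. Called lists, 20 of 31, were 19 of 31 under DESeq2 size factors and 16 of the 24 that could be tested at a mean count of 100. Without 1 library they were 11 to 17 of 30, lowest without library 2, for a cause that was not tested. Without length adjustment, Foxp3 against Bcl6 turned to -0.35, since counts without length favour longer transcripts. The correlation of the gene tables moved to 0.836 and the genes over 2-fold to 4807 among genes at 1 TPM or more, where fewer genes were compared. Detected list genes, 378 of 520, ranged from 316 at 5 TPM to 397 at 0.5 TPM, and the Treg core rank was at its ceiling of 100 in all settings, so that it could hardly show a move. Of the other 33 list ranks, 25 moved against random lists drawn from all genes above 0, a lower background. Th17-associated went to 97.5, Th2-associated to 98.5 and genes lowered in Treg to 99.0. Lists of other cell types moved as well: B cell to 93.3, CD8 T cell from 48.5 to 93.2, plasma cell to 77.4 and NK cell from 2.87 to 77.2. The stromal, endothelial and epithelial list reached only 0.72. Without 1 library, ranks of other cell types shifted, plasma cell from 24.7 to between 0.11 and 37.1 and B cell from 35.1 to between 25.2 and 52.6. The mean of any 2 libraries always lies within 1 SD of the mean of 3, so that limit cannot judge values without 1 library. Same-sign pairs were 24 without length, 25 in the whole-number table and 26 to 27 without 1 library. The size of the difference moved by over 1 SD in 11 of 24 pairs without length, besides the pair that turned, in 13 in the whole-number table and in 2 with a pseudocount of 1. Shared leading transcripts were 28 to 29. Depth limits small changes: 70% of simulated 1.5-fold changes were recovered. No paired analysis was possible because all libraries belong to 1 group.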

Other observations

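The tests of receptor and immunoglobulin gene classes, and the genes named here except Gzmb and Crtam, were chosen after their values were seen. Receptor beta chain V genes show how uneven the libraries were. Trbv13-2 held 9.71%, 25.7% and 15.4% of the counts on the 21 tested Trbv genes in libraries 1, 2 and 3, Trbv3 19.8%, 12.5% and 13.3%, and Trbv4 11.1%, 2.28% and 7.38%. Trbv16, at 6.51%, 5.91% and 5.93%, was nearly level. Of the 92 V genes that passed, 34 were highest in library 1, 23 in library 2 and 35 in library 3, and 79 differed over 2-fold. With the squared posterior SD added, 68 of the 105 tested V genes passed. Summed over the tested V genes, levels were 4613, 4430 and 4667 TPM in libraries 1, 2 and 3, so single segments differed while their sum was close to level.

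Immunoglobulin genes were also uneven, with 27 of 27 tested V genes and 10 of 10 tested C genes passing. Ighg2c had 0, 0 and 202 counts in libraries 1, 2 and 3, and Ighg2b 2, 4 and 137. The T-box factor gene Eomes had 6, 317 and 76 counts, and Crtam 83, 362 and 96. Itgae, which encodes CD103, had 1804, 1013 and 1679. Gzmb, by contrast, was highest in library 1, at 307, 236 and 200 TPM.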
